A study of Mus musculus with 8 samples.

How the data were processed

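Gene expression was measured in MAM326, a mouse mammary cancer cell line, after fluorescence-activated cell sorting into a GFP-positive and a GFP-negative fraction. Per the labels, cells were sorted 2 days after seeding, in 4 independent experiments at different passages, and Cy3-labelled cRNA was made from 20 ng of total RNA for each array. The series comprises 8 one-colour Agilent arrays, 4 of GFP-positive and 4 of GFP-negative cells. Groups and replicate numbers were taken from the labels. What drives GFP in these cells is not given in the sources used here.

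Each file held the scanner output of 1 array as made by Agilent Feature Extraction, which the submitters' processing notes name without a version. Per the file headers, the version was 10.7.3.1 with the protocol GE1_107_Sep09 and probe positions on the mouse build mm9. The deposited intensity values used here were the processed signal, which that program had already corrected for background, and, for 1 alternative, the mean signal and the median local background. The authors' steps after extraction are not given in the sources used here, and the deposited intensities of different arrays had not been scaled to each other.

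Each array carried 62976 spots, of which 59305 were not controls and represented 55681 probes. Spots marked by the extraction program as non-uniform or as population outliers were left out, 106 to 186 per array. The log2 processed signal of each array was set relative to its 75th percentile over the remaining non-control spots, and spots of one probe were averaged. Levels below are log2 values on that scale, so a level of 0 is the array's 75th percentile, and levels of different probes are not compared. No spot was saturated. Between 45.1% and 57.4% of the probes were well above background per array. The number of arrays limits the precision of every value, and probes near background are the least certain. The labels do not say which array came from which experiment, so p-values refer to the spread between these 8 arrays.

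Probes well above background on at least 4 of the 8 arrays were kept, 27591 in all, and each gene was represented by its brightest kept probe. This left 19694 features. Accessions of 27509 of the 55681 probes (49.4%) matched a table of RefSeq genes of GRCm38.p6, which was used for symbols only, and other probes kept the file's name. Of the features tested, 14149 carried a reference symbol. Positions are those the files give for the probe on mm9. Which exon or untranslated region a probe lies in was not analysed here. Where a gene was not well above background on any GFP-negative array, its difference is given as a bound: the mean GFP-positive level against the mean, over the GFP-negative arrays, of the higher of the lowest signal well above background and the probe's own signal.

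GFP-positive minus GFP-negative was fitted with limma 3.58.1 (lmFit and eBayes, two-sided moderated test, no replicate block) in R 4.3.3, with files read by data.table (version 1.17.8), with Benjamini-Hochberg adjustment and a threshold of 0.05. Errors beside log2 differences are standard errors of that fit, and errors beside levels are SDs over 4 arrays. Of 35 gene lists, which like the rule for named genes and the settings were fixed before the data were examined, the 34 with at least 5 measured members were tested with limma's camera at a preset correlation of 0.01 between genes, with adjustment over the lists. Camera with an estimated correlation and fry were alternatives. Each list's median was also placed among medians of 10000 random lists of the same size and similar brightness. Counts of list members past the threshold were made over all features and adjusted over the list alone.

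The rule for named genes took the 12 largest rises and the 12 largest falls among genes past the threshold whose groups did not overlap and that carry a gene symbol. From each list past its threshold, or with at least 3 members past the gene threshold, it took up to 4 members past the threshold with the largest differences. Lastly it took 18 mammary, stem cell and lineage genes whatever their result. Genes named outside the rule are said to be so where they appear.

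The steps were tested on simulated values for the same genes, drawn from the arrays' means and SDs with 200 of 19683 genes changed. The test for changed genes recovered 36.0% of changes of 0.5 on the log2 scale, 76.0% of changes of 1, 96.0% of changes of 2 and 92.0% of changes of 3, with 5 false calls. Of the simulated lists, 0 of 30 unshifted ones were called by camera, and the shifted one was called with both correlation settings. The simulated genes varied independently of each other. Genes of real lists can vary together, with an estimated correlation of 0.70 in the epithelial junction list. How often camera errs with such lists was therefore not shown by the simulation. A scan for runs of neighbouring genes, run on 14069 simulated genes, found the 1 lowered segment and 0 windows without it.

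The alternatives were the replicate block, normexp background correction with an offset of 50, quantile normalization, median centring, other filters on dim probes, outlier spots kept, the mean over a gene's probes, an intensity trend with a robust prior, array weights, and leaving out arrays. All arrays were on 1 slide and from 1 scan, so neither could be used as a block. The slide holds 2 rows of arrays, with both groups in each. Row 1 held GFP-negative replicates 2 and 4 and GFP-positive replicates 1 and 3, and had more spots well above background (30728 to 34446) than row 2 (27409 to 29127). Slide row was therefore added as a block, and fits within each row were made, after seeing the data. Within a row the groups hold different replicate numbers. A difference between the rows' results therefore cannot be told apart from a difference between replicate numbers or between experiments. Figures were drawn with matplotlib 3.10.9.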

Results

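Whole-transcriptome mRNA levels were measured on 8 one-colour arrays of sorted MAM326 cells, a mouse mammary cancer line, with 4 arrays of GFP-positive and 4 of GFP-negative cells. The study set out to describe the transcripts of a mammary cancer stem cell population, and the single comparison its labels define is GFP-positive against GFP-negative. Between 25112 probes (GFP-positive replicate 2) and 31970 probes (GFP-positive replicate 3) were well above background. Correlations between arrays across genes, which are not independent replicates, ran from 0.978 to 0.995. The first principal component held 40.1% of the variance, with GFP-positive replicate 3 at one end (score -56.2) and GFP-negative replicate 2 at the other (45.6).

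Of the features past the threshold, more were higher than lower in GFP-positive cells. Inpp5d, which encodes the inositol phosphatase SHIP1, targets of the tumour suppressor p53 such as Cdkn1a, and several carboxylesterases were among the genes that rose. Of 19694 features, 503 passed an adjusted p of 0.05 in limma, 357 higher and 146 lower in GFP-positive cells, and 434 of them carried a reference symbol. The rises were larger, with a median of 1.07 on the log2 scale against 0.46 for the falls: 193 features were at least 2-fold higher and 2 at least 2-fold lower. At an unadjusted p under 0.05 falls outnumbered rises, with 1542 features higher and 2982 lower, as they did past the threshold with array weights (796 higher, 1020 lower) and with an intensity trend and robust prior (535 higher, 629 lower). All 503 had groups that did not overlap. Over all features the groups of 16.7% did not overlap, against 2.86% by chance. With slide row as a block 277 features passed (239 higher and 38 lower), and within the rows, 2 arrays against 2, 1046 passed in row 1 and 0 in row 2 in limma, where 2149 had an unadjusted p under 0.05. The count was 422 without GFP-positive replicate 2. It was 318, 222, 228 and 200 without GFP-negative replicates 1, 2, 3 and 4, and 150, 223 and 282 without GFP-positive replicates 1, 3 and 4.

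Inpp5d was at -0.59 ± 0.28 (SD, n = 4) in GFP-positive and -3.75 ± 0.60 in GFP-negative cells, a rise of 3.16 ± 0.29 or 8.93-fold (adjusted p = 0.00176, limma). Its probe lies on chromosome 1 from 89616958 to 89617017 (mm9), and no other probe of it was kept. What drives GFP is not given in the sources used here, so whether the sort itself selected for expression of Inpp5d is not known. The rise was 3.69 within slide row 1 and 2.62 within row 2. Sytl1, a synaptotagmin-like membrane trafficking protein, rose 9.72-fold (3.28 ± 0.22, adjusted p = 0.000550). Cpz, a carboxypeptidase, rose by 3.53 ± 0.21 and was well above background on 1 of the 4 GFP-negative arrays. Robo3, an axon guidance receptor, rose by 3.17 ± 0.46 (adjusted p = 0.0144, and 0.0610 without GFP-positive replicate 1). It also lost its call without GFP-positive replicate 3 and without GFP-negative replicate 4. The other 11 of the 12 largest rises passed the threshold without each of the 8 arrays in turn, and all 12 passed with slide row as a block. Of the 40 genes named here by rule that passed, 17 did so without each of the 8 arrays: these 11, Ints13, Rangrf, Eda2r, Trp53inp1, Cdkn1a and Cd68. The other 23 lost their call without GFP-positive replicate 1, most of them without further arrays too, and Cd14, E2f8 and Hsph1 without any 1 of the 8.

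Among the 12 largest rises were 3 Ces2 carboxylesterases, neighbouring genes on chromosome 8. Ces2e rose by 3.97 ± 0.20 (adjusted p = 0.000123), from a level of -3.48 ± 0.42 to 0.49 ± 0.11. Ces2c and Ces2g were not well above background on any GFP-negative array and were at least 7.84-fold and 4.51-fold higher in GFP-positive cells (adjusted p = 6.38e-05 and 0.00213). These genes are close paralogs, so how far their probes detect each other is uncertain. Of the remaining large rises, Svop, a synaptic vesicle protein, was at least 5.71-fold higher, and Ms4a10, a membrane protein, at least 8.77-fold. Slc2a9, a urate and sugar transporter, was at least 3.70-fold higher. Ppp2r2c, a regulatory subunit of protein phosphatase 2A, and Mst1, which encodes macrophage-stimulating protein, were at least 3.63-fold and 2.94-fold higher. Their adjusted p values lay between 0.000550 and 0.00528. These bounds hold for the processed signal only. With normexp, whose added offset of 50 shrinks differences of dim probes, the log2 differences were 1.20 for Ces2c, 0.81 for Ces2g, 1.13 for Svop, 1.37 for Ms4a10, 0.64 for Slc2a9, 0.79 for Ppp2r2c and 0.64 for Mst1, below the bounds though past the threshold, and those of Ces2e, Cpz, Inpp5d and Robo3 were 2.84, 1.49, 2.06 and 2.55.

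Most genes of the list of cell cycle inhibitors and p53 targets were higher in GFP-positive cells. Of its 25 members, all measured, 21 had a positive and 4 a negative sign. Past the threshold 13 rose and 0 fell, 15 rose when adjusted over the list alone, and the median difference was 0.70. In limma 15 members were higher and 0 lower at an unadjusted p under 0.05. Camera gave an adjusted p of 1.04e-14, and the list was the only one of 34 past the threshold with an estimated correlation (adjusted p = 0.0272). Over all 27 alternatives its adjusted p ran from 1.58e-17 to 0.0272. Cdkn1a, the cyclin-dependent kinase inhibitor p21, rose 4.64-fold (2.21 ± 0.28, adjusted p = 0.00753), and its other 2 kept probes, annotated to other transcript accessions, differed in the same direction, by 1.85 and 2.82. Trp53inp1, a stress-induced p53 target, rose 5.26-fold (2.39 ± 0.25, adjusted p = 0.00366). Ccng1, cyclin G1, rose 3.54-fold (1.82 ± 0.26, adjusted p = 0.0135), but did not pass without GFP-positive replicate 1 (adjusted p = 0.0606) or without GFP-negative replicate 4. Eda2r, a receptor of the tumour necrosis factor family, was not well above background on the GFP-negative arrays and was at least 3.63-fold higher (adjusted p = 0.00411), with a log2 difference of 0.57, below that bound, with normexp. Trp53, looked up after its value was seen, was at 1.37 ± 0.07 and 1.38 ± 0.13, a difference of -0.01 (adjusted p = 0.951). The list's median was 0.82 within slide row 1 and 0.58 within row 2.

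**Figure D1:**
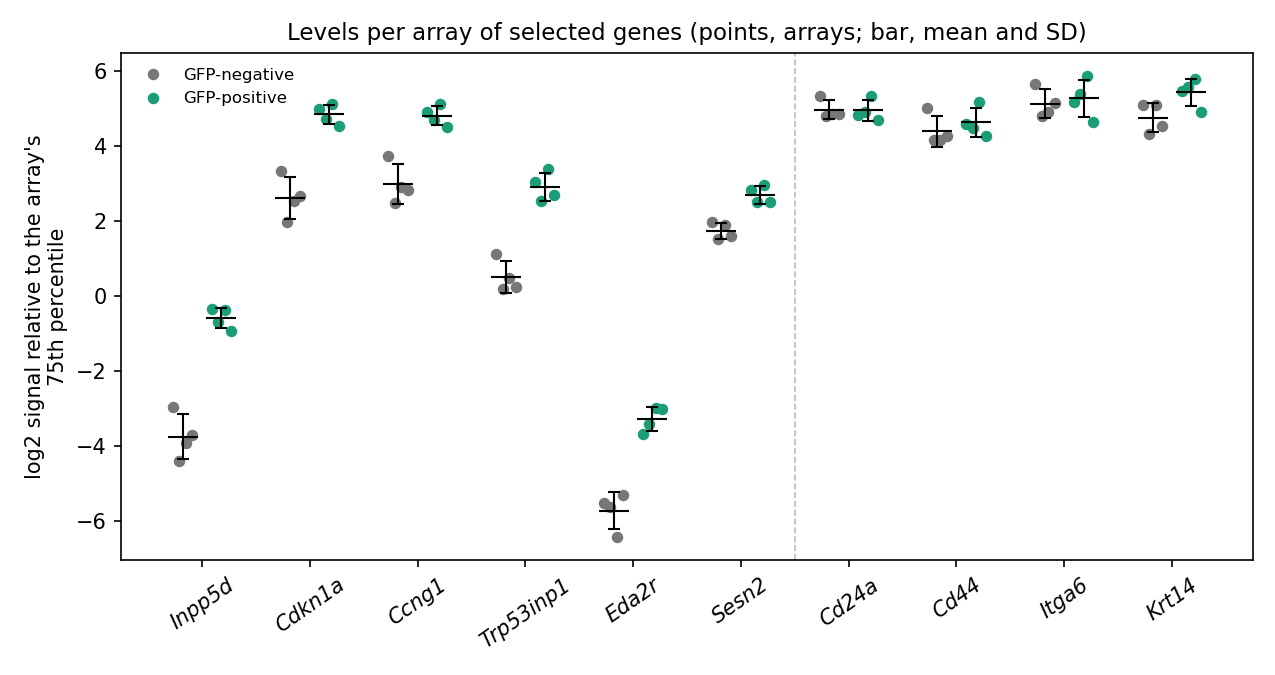
Level of 10 genes on each array (vertical axis, log2 signal relative to the array's 75th percentile). Points are arrays, grey for GFP-negative and green for GFP-positive, and bars are the mean and SD of 4 arrays. Inpp5d and 5 p53 targets, left of the dashed line, have separate groups, with Inpp5d at -3.75 and -0.59 on average, and the groups of the 4 stem or basal cell genes on the right overlap.

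The falls were small. Serpina3g, a serine protease inhibitor with close paralogs, fell by 1.33 ± 0.25 (adjusted p = 0.0380) and Slc2a3, the glucose transporter GLUT3, by 1.31 ± 0.21 (adjusted p = 0.0207), with -0.73 and -0.69 with normexp. Of the 12 largest falls, 6 were genes on distal chromosome 6, between 146498344 and 148138077 (mm9): Ints13, a subunit of the Integrator complex (-0.98 ± 0.11, adjusted p = 0.00417), Ergic2 (-0.88), Mrps35 (-0.79), Med21 (-0.72), Ppfibp1 (-0.68) and Fgfr1op2 (-0.68). The other 4 were Rasgrp2 (-0.90), Taf9b (-0.88), Plekhg4 (-0.80) and Rangrf (-0.69), on chromosomes 19, X, 8 and 11. Over the alternatives the falls of Rasgrp2 and Taf9b were as small as -0.38 and -0.36. Only Ints13 and Rangrf of the 12 passed the threshold without each of the 8 arrays. The other 10 lost it without at least 1 array, GFP-positive replicate 1 in every case, with adjusted p values up to 0.156, that of Taf9b, and 4 of the 12 passed with slide row as a block.

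**Figure D2:**
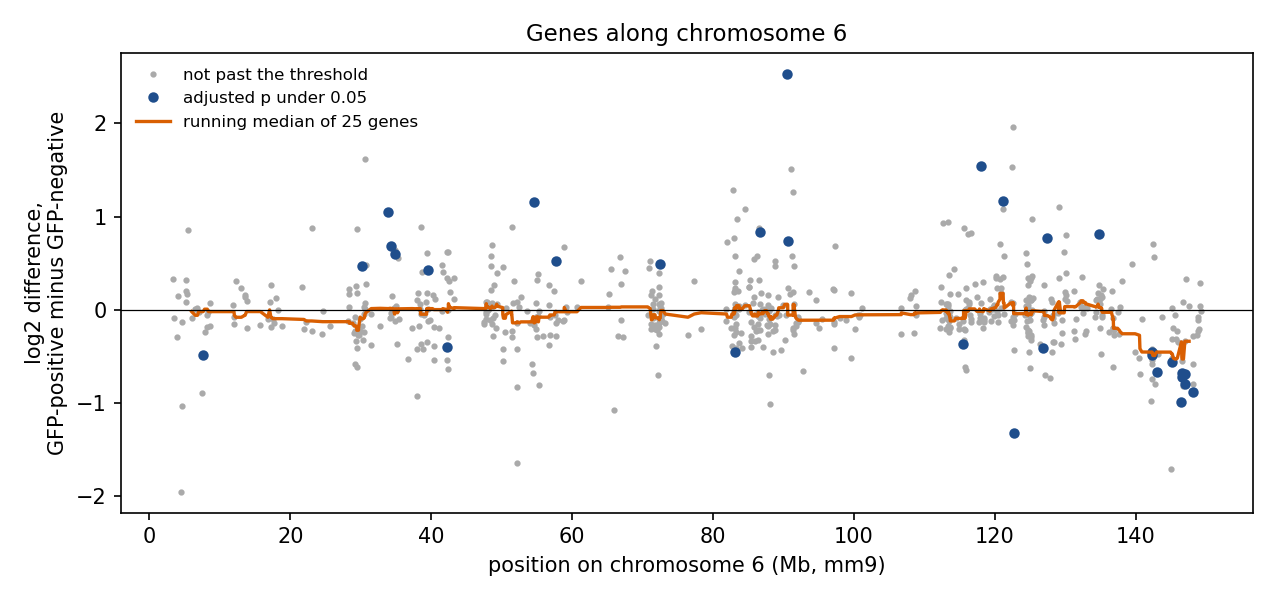
Log2 difference between GFP-positive and GFP-negative cells (vertical axis) of genes with a reference symbol along chromosome 6 (horizontal axis, Mb on mm9). Blue points passed an adjusted p of 0.05, grey points did not, and the line is the running median of 25 neighbouring genes, which reaches -0.53 near the distal end.

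Of the 18 mammary, stem cell and lineage genes named whatever their result, only Inpp5d passed the threshold. Cd24a differed by -0.02 ± 0.17, Cd44 by 0.24 ± 0.25, Itga6 by 0.15 ± 0.28, Itgb1 by -0.07 ± 0.16, Itgb3 by -0.07 ± 0.24, Prom1 by -0.08 ± 0.61 and Procr by 0.55 ± 0.37 (adjusted p from 0.414 to 0.966). The other kept probe of Itgb1 and that of Itgb3 had the opposite sign, and the other 3 probes of Cd44 ran from -0.0079 to 0.65. Epcam differed by 0.48 ± 0.28 and Vim, the mesenchymal filament protein vimentin, by -0.79 ± 0.41. Among keratins, Krt5 and Krt14 of basal cells differed by 1.18 ± 0.32 (adjusted p = 0.0911) and 0.67 ± 0.24, and Krt8 and Krt18 of luminal cells by 0.39 ± 0.22 and 0.18 ± 0.17. Mki67, a marker of dividing cells, differed by -0.29 ± 0.13 (adjusted p = 0.235). Under other settings Krt5 passed with array weights (1.24, adjusted p = 0.0335), and within slide row 1 Krt5, Krt14, Epcam and Krt8 passed (1.84, 1.19, 1.19 and 0.92, adjusted p = 0.0365, 0.0381, 0.0247 and 0.0407). Within row 2 they differed by 0.51, 0.15, -0.23 and -0.14 and did not pass. Aldh1a1, Kit and Lgr5 were well above background on 2, 0 and 1 of the 8 arrays and were not tested.

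As a whole, the list of mammary stem and cancer stem cell markers was higher in GFP-positive cells by camera (median 0.24, adjusted p = 0.0153), with 1 of 17 measured members past the threshold, Inpp5d, to which the same limit applies, and 3 higher and 1 lower when adjusted over the list alone. Its adjusted p was 0.556 with an estimated correlation, and its median was 0.42 within slide row 1 and -0.17 within row 2. Lists of basal, luminal progenitor and mature luminal markers were also higher by camera (medians 0.13, 0.29 and 0.23, adjusted p = 0.0153, 0.0310 and 0.0153), each with an adjusted p of 0.556 with an estimated correlation. Wnt4, a paracrine signal of mature luminal cells, rose by 1.02 ± 0.18 (adjusted p = 0.0347), and Cd14, a luminal progenitor and macrophage surface protein, by 0.56 ± 0.11 (adjusted p = 0.0499). Over the lists alone, 3 mature luminal members were higher and 1 lower, 1 luminal progenitor member was higher, and 0 basal members passed in limma, over all features or the list alone, with 3 higher at an unadjusted p under 0.05. Within slide rows 1 and 2 the medians were 0.23 and 0.07 for the basal list, 0.22 and 0.49 for luminal progenitors and 0.71 and -0.17 for mature luminal cells. The basal list lost its call without GFP-positive replicate 2 (adjusted p = 0.0876) and the mature luminal list without GFP-negative replicate 4 (0.0712). The luminal progenitor list lost it without GFP-negative replicates 1 and 3 and GFP-positive replicates 2 and 4, with adjusted p up to 0.0918.

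Epithelial junction and identity genes, such as claudins and desmosomal proteins, had a higher median in GFP-positive cells (0.56, camera adjusted p = 8.20e-09; adjusted p = 0.557 with an estimated correlation, which was 0.70 between the genes). Of the 30 genes 29 had a positive sign and 0 passed the threshold in limma, over all features or adjusted over the list alone, with 11 higher at an unadjusted p under 0.05. Of the 35 splits of the arrays into 4 and 4, 5 gave a median as large in size (exact permutation p = 0.143). The splits ignore replicate number and any experiment shared across numbers, so they cannot decide on a difference between paired arrays. At every number the GFP-positive array averaged higher over the list (2.84 against 2.48, 2.57 against 1.74, 2.92 against 2.51 and 2.29 against 1.77). Whether arrays of one number share an experiment is not known. With GFP-negative replicates 1 to 4 set beside GFP-positive replicates 3, 4, 1 and 2, their most correlated arrays, the GFP-positive array also averaged higher each time. That matching was picked from these data and was not tested. The median was 1.20 within slide row 1 and -0.11 within row 2, where the GFP-negative arrays averaged 2.48 and 2.51 over the list, against 1.74 and 1.77 for those of row 1. The GFP-positive arrays averaged 2.57 and 2.29 in row 2 and 2.84 and 2.92 in row 1. Mesenchymal transition genes, not past the threshold in the fit of all arrays (median -0.27, camera adjusted p = 0.337), had medians of -1.01 in row 1 and 0.21 in row 2. In each row replicates 1 and 3 of one group were set against 2 and 4 of the other, so row, replicate number and experiment cannot be told apart.

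**Figure D3:**
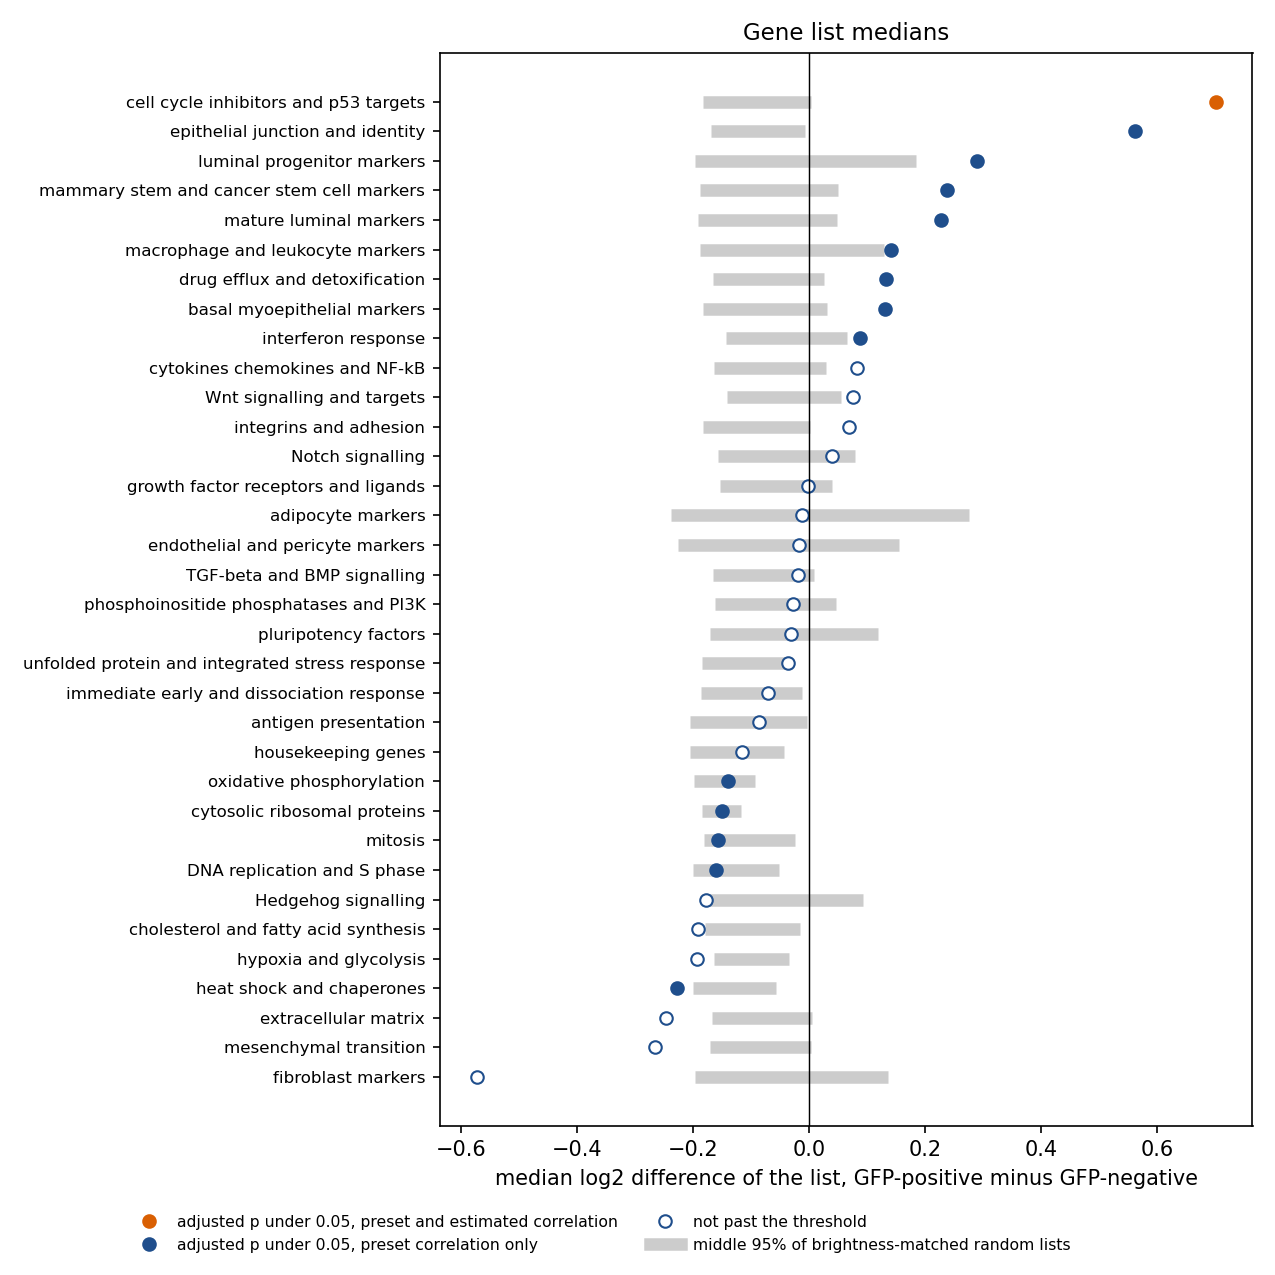
Median log2 difference between GFP-positive and GFP-negative cells (horizontal axis) of the 34 gene lists tested (vertical axis). Filled points passed an adjusted p of 0.05 in camera, the orange one also with an estimated correlation, open points did not, and grey bars are the middle 95% of medians of brightness-matched random lists. The p53 target list, at 0.70, lies farthest to the right.

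Lists of ribosomal, respiratory, cell cycle and chaperone genes were slightly lower by camera, while that of housekeeping genes did not pass (median -0.12, adjusted p = 0.267). Camera called cytosolic ribosomal proteins (median -0.15, adjusted p = 0.00150), oxidative phosphorylation (-0.14, 0.0122), DNA replication and S phase (-0.16, 0.00807), mitosis (-0.16, 0.0298) and heat shock and chaperones (-0.23, 0.0122) lower in GFP-positive cells. With an estimated correlation their adjusted p values were 0.556 for the heat shock list and 0.582 for the others. Of 29 replication genes 2 fell, Cdc6, a loading factor of replication origins (-0.51 ± 0.10, adjusted p = 0.0430), and E2f8, a repressor of the E2F family (-0.37 ± 0.07, adjusted p = 0.0463), and 5 fell when adjusted over the list alone. In the heat shock list Hsph1 fell by 0.48 ± 0.09 (adjusted p = 0.0367) and Cryab, a small heat shock protein, rose by 0.80 ± 0.11 (adjusted p = 0.0105), with 8 lower and 1 higher when adjusted over the list alone. Of the ribosomal, oxidative phosphorylation and mitosis genes 0 passed in limma, over all features or adjusted over the list alone, and 8, 10 and 9 were lower at an unadjusted p under 0.05. Within slide rows 1 and 2 the medians were -0.23 and -0.07 for ribosomal proteins, -0.26 and -0.024 for oxidative phosphorylation and -0.27 and -0.06 for replication. For mitosis they were -0.15 and -0.09, and for heat shock -0.28 and -0.19. With quantile normalization none of these 5 lists was called. Their medians were then -0.018 for ribosomal proteins, -0.014 for oxidative phosphorylation, -0.07 for replication, -0.07 for mitosis and -0.15 for heat shock. The mitosis list lost its call without GFP-negative replicates 1 and 4 and GFP-positive replicates 3 and 4 (adjusted p up to 0.0877), and oxidative phosphorylation without GFP-positive replicate 3 (0.0994).

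Further lists were higher by camera with few members past the threshold. In the macrophage and leukocyte list (median 0.14, adjusted p = 0.0310; adjusted p = 0.556 with an estimated correlation) Cd68, a lysosomal glycoprotein abundant in macrophages, rose 2.00-fold (1.00 ± 0.11, adjusted p = 0.00436), and Cd14 rose as above. Of this list 2 members were higher and 1 lower when adjusted over the list alone. In the interferon list (median 0.09, adjusted p = 0.0355; adjusted p = 0.750 with an estimated correlation) Usp18, an interferon-induced protease, rose 2.25-fold (adjusted p = 0.0296). It was the only member higher when adjusted over the list alone. Its log2 difference of 1.17 was as low as 0.64 over the alternatives. In the drug efflux and detoxification list (median 0.13, adjusted p = 0.0258; adjusted p = 0.557 with an estimated correlation) Aldh2, mitochondrial aldehyde dehydrogenase, rose by 0.67 ± 0.12 (adjusted p = 0.0297), and 2 were higher when adjusted over the list alone. The interferon median was -0.31 in slide row 1 and 0.49 in row 2, that of drug efflux -0.0097 and 0.28, and that of the macrophage list 0.09 and 0.11. The macrophage list lost its call without GFP-negative replicates 1 and 2 and GFP-positive replicates 2 and 4 (adjusted p up to 0.0804). The interferon list lost it without replicates 1 and 4 of either group (up to 0.606), and drug efflux without GFP-positive replicate 2 and GFP-negative replicate 3 (up to 0.197). All 14 lists called by camera were called with slide row as a block.

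The unfolded protein and integrated stress response list did not shift (adjusted p = 0.611), but 1 member rose and 2 fell, the same numbers as adjusted over the list alone. Sesn2, a stress-induced p53 target, rose by 0.95 ± 0.15 (adjusted p = 0.0195), and Asns and Psat1, enzymes of asparagine and serine synthesis, fell by 0.48 ± 0.08 and 0.46 ± 0.08 (adjusted p = 0.0252 and 0.0347). The other 19 lists tested did not pass. They covered Wnt, Notch, Hedgehog, TGF-beta and phosphoinositide signalling, growth factors, pluripotency, integrins, mesenchymal transition, matrix, early response, hypoxia, cholesterol synthesis, antigen presentation, cytokines, housekeeping genes, and fibroblast, endothelial and adipocyte markers, with adjusted p values from 0.0751 (hypoxia and glycolysis) to 0.762 (fibroblast markers). Their members past the threshold, chosen here after their values were seen unless named above, were Notch3 (2.51), Nlrc5 (2.06), Tap1 (1.53), Btg2 (1.16), Inhbb (0.86), Cd81 (0.81), Gsn (0.63) and Pik3r3 (0.61), all higher, besides Inpp5d and Wnt4, and Slc2a3, which fell. In 9 of these lists, among them fibroblast markers, antigen presentation and phosphoinositide signalling, the median was negative and the direction of the test upward. Red blood cell genes, with 2 measured members, were not tested as a list.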

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

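The test of slide row, the use of the planned fits without single arrays to judge the p53 pattern, and the use of splits to judge a list's median were chosen only after the result was seen. The counts of splits for features and lists and the further p53 list were set before.

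Of 182 groups of 4 arrays examined, 12 held 1 array far from the other 3, against 9.1 by chance at 1 in 20. In GFP-negative cells, Cd24a (5.33, others 4.78 to 4.85), Cd44 (5.00, others 4.14 to 4.25), Procr (2.66, others 1.40 to 1.47) and the endothelial and pericyte list (-0.29, others 0.19 to 0.27) stood apart on replicate 1. Med21 stood apart on replicate 2 (5.36, others 4.98), and Prom1 on replicate 4 (-3.57, others -1.52 to -1.46). On replicate 3 the phosphoinositide list was at 0.99 (others 0.83 to 0.85) and the drug efflux list at 1.16 (others 1.56 to 1.61). In GFP-positive cells, Prom1 (-3.50, others -1.70 to -1.47) and Asns (6.41, others 6.18 to 6.20) stood apart on replicate 2. The integrin list did so on replicate 3 (2.48, others 2.34 to 2.36) and Ppfibp1 on replicate 4 (5.05, others 4.77 to 4.81).

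Of the 35 splits of the 8 arrays into 4 and 4, 1 gave as many changed features as the real one, the real split itself, with 503 against at most 15 for any other. Chance is therefore argued against for the count of features, as far as 35 splits can tell. For the lists, 2 of the 35 splits gave as many past the threshold, with 14 for the real split and 14 for the highest other, so chance is not excluded for the count of 14 lists. That other split set GFP-negative replicate 1 with GFP-positive replicates 1, 2 and 3 against the rest and does not follow slide row.

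The first pattern is the rise of the p53 target list. A single array is argued against as the source, since without any 1 of the 8 arrays the median stayed at 0.64 or above, and so is slide row, since the lower of the medians within rows was 0.58. The median of 0.70 was larger than in any other of the 35 splits (highest 0.51; exact permutation p = 0.0286, the smallest these splits can give). Higher p53 activity in GFP-positive cells is a candidate explanation: a further list of 72 measured p53 targets, without genes whose values had been seen, had a median of 0.16, above 100% of 10000 brightness-matched random lists, which met the bound set beforehand, with 4 members past the threshold, all higher, and 50 of positive sign. Barred from it were members of the fixed lists and genes already seen, among them Sytl1, Ces2c, Ces2e and Ces2g. This left 81 of the 95 genes written, so its median does not speak for those large rises. After 2 of the 35 splits were seen to give a median as large (exact permutation p = 0.0571, highest other 0.22), and with p = 0.0576 by camera with an estimated correlation, the explanation was left open, as are other causes of higher p53 target expression, which were not tested.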

How the results depend on the processing

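Slide row and the fits within rows were chosen after seeing the data, and the other alternatives before. The 503 changed features (357 higher, 146 lower) became 782 (361 lower, 53.8% higher against 71.0%) with normexp, 1164 (629 lower) with an intensity trend and robust prior, 1816 (796 higher, 1020 lower) with array weights and 151 (149 higher, 2 lower) with no filter on dim probes. Among probes well above background on all arrays 323 were lower, and with quantile normalization 82. The cause was not tested, except that 34761 features were tested without the filter. At least 2-fold changes numbered 195, and 4524 features had an unadjusted p under 0.05. Slide row as a block left 277 (38 lower), 272 of them among the 503. Within slide row 1 there were 1046 (624 higher, 422 lower), 220 of them among the 503. Within slide row 2 there were 0 (0 higher, 0 lower) in limma, with 2149 at an unadjusted p under 0.05. With fewer arrays, without single arrays or replicate numbers, counts ran from 106 to 422 (103 to 302 higher, 1 to 120 lower).

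Replicate numbers are shared between the groups, but over all features the arrays with the same number did not deviate together. The correlations of their deviations ran from -0.03 to 0.18, with 1 of 4 over 0.1, and 0 of 8 arrays correlated best with their own number. Some lists separated replicates 1 and 3 from 2 and 4 in both groups. Experiments shared by number would give this, and so would the cross-number pairs below. Replicates 1 and 3 lay above 2 and 4 in both groups for the epithelial junction list (2.48 and 2.51 GFP-negative, 2.84 and 2.92 GFP-positive). For the mesenchymal list they lay below (2.22 and 2.24, 2.02 and 1.83). Arrays with different numbers correlated from -0.53 to 0.65. The highest values fell in a one-to-one matching. GFP-negative replicate 1 went with GFP-positive replicate 3 (0.60), 2 with 4 (0.65), 3 with 1 (0.43) and 4 with 2 (0.34). The low same-number values therefore do not exclude that experiments are shared across numbers. Neither the main fit nor the splits of the arrays take such sharing into account, and the replicate block pairs by number. No pairing was taken from these values. With the replicate block, 214 features passed, 188 higher and 26 lower, and 14 lists, 13 of them among the 14.

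The 14 lists became 6 with quantile normalization, 1 with an estimated correlation, 1 with fry's directional test and 20 with its mixed test, which asks another question. Without arrays they ran from 8 to 14. The p53 list passed in all 27 alternatives. Within slide row 2 the medians of the epithelial junction, stem cell marker and mature luminal lists turned to -0.11, -0.17 and -0.17 (the test's direction stayed upward for the last 2), and the direction of the test for oxidative phosphorylation turned (median -0.024). There, mesenchymal transition (0.21), cholesterol and fatty acid synthesis (0.24), antigen presentation (0.21) and fibroblast markers (0.55) were called higher, against -1.01, -0.58, -0.38 and -1.66 within row 1, where the first 2 were called lower. Within slide row 1 the interferon list turned to -0.31 and drug efflux to -0.0097. These turns between rows cannot be told apart from differences between replicate numbers. Nor can they be told apart from differences between experiments, since each of the most correlated cross-number pairs was divided between the rows. Of the 40 named genes past the threshold, 17 passed without each of the 8 arrays and 24 with slide row as a block. All 40 kept their sign within both rows, which was certain beforehand because their groups did not overlap. Quantile normalization changed the median difference of all features from -0.06 to -0.03. Slide and scan could not be used as blocks, with 1 of each. Low signal over background limits genes such as Svop and Ppp2r2c, whose differences are bounds that hold for the processed signal and not with normexp.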

Other observations

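The scan of neighbouring genes, the test of brightness and the genes named in this part were chosen after the results were seen. Several single genes outside the rule for named genes rose. Notch3, a Notch receptor, rose 5.71-fold (2.51 ± 0.24, adjusted p = 0.00215), while the Notch list did not shift (adjusted p = 0.452). Tap1, a peptide transporter of antigen presentation, rose by 1.53 ± 0.13 (adjusted p = 0.00126), and Nlrc5, an activator of class I genes, by 2.06 ± 0.28 (adjusted p = 0.0105; well above background on 2 of the 4 GFP-negative arrays, with 0.43 for its other kept probe), while H2-K1 differed by -0.27 and B2m by -0.06. Zfp750 and Grhl3, transcription factors of epidermal differentiation, rose by 2.91 ± 0.37 (adjusted p = 0.00797) and 1.28 ± 0.18 (adjusted p = 0.0137). Ptp4a3, a phosphatase, rose by 2.18 ± 0.19 (adjusted p = 0.00126).

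The collagen gene Col1a1 varied between arrays of one group. It differed by -2.12 ± 1.19 (limma adjusted p = 0.325), with SDs of 1.98 in GFP-positive and 1.89 in GFP-negative cells. GFP-negative replicates 1 to 4 were at 1.64, 5.94, 4.95 and 5.03, and GFP-positive ones at 2.11, 3.32, -0.44 and 4.08. By number, Col1a1 was higher in GFP-positive cells at replicate 1 and lower at the others. Set beside GFP-positive replicates 3, 4, 1 and 2, the most correlated arrays, it was lower each time. That matching was picked from the data and was not tested. The fibroblast list averaged from -1.74 (GFP-positive replicate 3) to 0.60 (GFP-negative replicate 2). Its camera direction was upward although its median was -0.57, and it did not pass (adjusted p = 0.762), except within slide row 2, where it was called higher (0.55, adjusted p = 0.0402), against -1.66 (adjusted p = 0.0894) within row 1.

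Running medians of 25 neighbouring genes were scanned over 14077 genes with a reference symbol. Besides chromosome 6, 2 regions held windows with medians above the highest window median of 95% of shuffled orders. Window medians reached 0.70 on chromosome 3 and 0.32 on chromosome 15, and the medians below are those of the whole regions. On chromosome 3, from 90292316 to 94564090 (mm9), 44 genes with S100, Sprr and Lce families of the epidermal barrier had a median of 0.25, 1 of them past the threshold. On chromosome 15, from 73035632 to 75455590, 28 genes that include the Ly6 family had a median of 0.28, with 2 past the threshold. Both hold paralogs, and how far their probes detect each other was not tested. The chromosome 3 median was reached in size by 2 of the 35 splits of the arrays, the real one included, and the chromosome 15 median by the real one alone (highest other 0.27), in regions chosen from the real split.

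The second pattern weighed is lower expression of distal chromosome 6 genes in GFP-positive cells, from 136757181 to 149283985 (mm9), where 52 of 63 genes were lower, with a lowest window median of -0.53. A chance arrangement of the genes is argued against, since 0 of 1000 shuffles of the gene order gave a window median as low (lowest -0.36). Shuffles break any variation that neighbouring genes share. Another split of the arrays gave this window a median of 0.40 in size, beyond that of every shuffle. The real split gave the largest of the 35, in a window chosen from it. The window median lay at the 0th percentile of 10000 brightness-matched random lists (middle 95% from -0.18 to 0.01). Those lists were not picked as the lowest of many, as the window was, so this percentile cannot decide on a brightness trend. With features split into twentieths by brightness, the lowest median was -0.16. The window median was -0.60 and -0.49 within slide rows 1 and 2, in a window chosen because it was the lowest. A copy number difference of the segment between the fractions is a candidate explanation: of 23 features of the segment that have no reference symbol and did not enter the scan, 87.0% were lower, against 61.8% of such features on all chromosomes, though their median was only -0.21, against -0.34 for the 63 genes. Regulation of the whole segment would look alike, no DNA was measured here, and both stay open.

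The third pattern is the small fall of the ribosomal, oxidative phosphorylation, replication, mitosis and heat shock lists. Medians went from 0.07 in the dimmest twentieth of features to -0.15 in the brightest, and from -0.09 to -0.01 with quantile normalization, where the medians of the ribosomal, oxidative phosphorylation, replication and mitosis lists were -0.018, -0.014, -0.07 and -0.07 and that of heat shock was -0.15, reduced from -0.23, none of them called. For the ribosomal, oxidative phosphorylation, replication and mitosis lists such a brightness trend may account for the fall, since their medians lay at the 9.76th percentile or above among brightness-matched random lists. For the heat shock and chaperone list it is argued against as the whole cause, since the median lay at the 0.300th percentile, although another split of the arrays gave a median nearly as large (0.22 against 0.23). What produced the trend, in the arrays or in the cells, was not tested.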
